A study of Arabidopsis thaliana with 4 samples.

How the data were processed

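Gene expression was measured in Arabidopsis thaliana Col-0 seedlings on 4 Agilent 2-colour oligonucleotide arrays of 1 slide. Per the labels, seedlings were raised in a cycle of light and dark on agar with sucrose. At 14 days they were taken off the agar, equilibrated in water and moved to water with 20 µM cis-cinnamic acid in the light. The labels also give DMSO for the treatment. Seedlings were collected at 0 h (the control), 2 h and 6 h. On every array the treated RNA carried Cy5 and the 0 h control RNA carried Cy3, so dyes were not swapped. There were 2 arrays at 2 h and 2 at 6 h, and samples were grouped by the time point in the labels. The series description counts 2 control replicates, and the labels do not tell which control RNA lay on which array. The labels call the replicates biological, and nothing says that they came from separate cultures, so the p-values measure only the spread between these samples. The control RNA was measured on every array as the reference channel, and no sample without the compound was taken at 2 h or 6 h.

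The deposited scanner files hold, per the file headers, the mean pixel intensity of each spot and the median intensity of its local background in both channels. They also hold Agilent's own log10 ratio of Cy5 over Cy3, which the authors' software computed after background detrending and dye normalization, per the file headers. The extraction software was Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 8.5.1.1 per the submitters' processing notes. The authors' table of the whole series was deposited with no stated scale. Its values were set against the scanner values spot by spot, and they matched the log10 ratio of Cy5 over Cy3 within 0.001 or 1% for all but 20, 1, 4 and 3 spots of the arrays 2 h replicate 1, 2 h replicate 2, 6 h replicate 1 and 6 h replicate 2. The column medians were 0, and 377, 58, 74 and 90 spots were blank. Scale, centring and direction of that table therefore follow from the scanner values, and the table was used only as an alternative.

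Each array had 45220 spots, of which 43803 were not controls and held 43603 different probes. The median Cy5 intensity was 492, 386, 403 and 351 on the 4 arrays in the order above and the median Cy3 intensity was 228, 244, 212 and 242. In Cy5, 69.0%, 68.6%, 68.7% and 65.3% of the spots were well above background, against 61.9%, 66.3%, 65.3% and 63.7% in Cy3. No spot was saturated (0 on each array). Outlier spots numbered 310, 44, 45 and 75. With 2 arrays per time point, the number of arrays limits the precision.

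Backgrounds were corrected with the normexp model (offset 50), spots marked by Agilent as non-uniform or population outliers and control spots got no weight in the loess normalization within each array and were then left out, and spots of 1 probe were averaged. The background model departs from the plan written before the data were examined. As planned, it was to be fitted on all spots. On 2 h replicate 1, 8 spots had a local background that exceeded their own signal by more than the offset, and they pulled the modelled background mean to −448 in Cy5 and −551 in Cy3, against −7.79 to −10.9 and 5.89 to 11.1 on the other arrays. That squeezed the ratios of this array: the SD of its log2 ratios was 0.250, and the SD among repeated spots of a probe was 0.0155 against 0.0568 to 0.0591 on the other arrays. These 8 spots were therefore left out of the background model and of the values. The modelled means then became −9.39 and 4.01, the SD of the log2 ratios 0.404 and the SD among repeated spots 0.0577. The other arrays held 0 such spots. This change was made after the planned fit had been seen to call 0 genes at 2 h. The counts of genes as planned are given beside the ones reported at 2 h, and in the closing section for 6 h and the difference.

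Probes were kept if Agilent's call of well above background held in at least 1 channel on both arrays of at least 1 time point and if at least 3 arrays gave a value, which left 29506 probes. Of the 43603 probes, 37540 carried 1 locus name in the files, 873 several and 5190 none, and only probes with 1 locus were named. The deposited files name 28479 loci, of which 28074 were found in the reference table of gene names (no reference genome was used here). A gene was represented by its kept probe with the highest mean log2 intensity, which gave 19973 genes, 5534 of them with more than 1 kept probe. Positions are those of the probes as the deposited files give them, on the build that the headers name as ath1:Jan2004.

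Log2 ratios were tested with limma (lmFit and eBayes). There was 1 coefficient per time point, tested against 0, over all 4 arrays with a shared spread per probe. The fit had 2 residual and 2.79 prior degrees of freedom. It treated the 4 arrays as independent, although some may share control RNA. Deviations from the group means of same-numbered arrays had a correlation of 0.43 across genes. The p-values do not allow for this, except where the replicate number was a block. The difference between 6 h and 2 h was a contrast in the same fit. A gene passed at an adjusted p (Benjamini-Hochberg over the kept probes) under 0.05, and values are given as log2 ratio ± standard error (n = 2 arrays). A gene with a value on 1 array of a time point took its spread from the other time point and the prior, which applies to 2 of the genes that passed at 2 h and 3 at 6 h. The 28 gene lists with 567 members were written before the data were examined. The symbols of 546 members matched the reference names at their locus, 21 loci had no name there, and 531 members had a kept probe. Lists were tested with limma's camera against all other genes (19786 genes, preset correlation 0.01, in both directions, Benjamini-Hochberg over the 27 lists with at least 5 kept members). Camera with an estimated correlation and fry were the alternatives. With an estimated correlation camera tests on the residual degrees of freedom, which were 2 here, so it had little power. A list that it did not call is therefore left undecided by it.

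The genes named were chosen by a rule set beforehand. For 2 h and for 6 h these were the 10 genes with the largest rise and the 10 with the largest fall among those that passed with the same sign on both arrays, and for the difference between the times the 5 largest in each direction among genes whose arrays did not overlap between the times. For each list they were up to 4 members with the largest log2 ratio in size among those that passed or, where none passed, up to 2 members given as values. Genes named outside this rule are said to be so. At 2 h GH3.1, ARD3, AT5G24100, AT1G07050, GA2OX2, ERF71, EXPA18 and XTH19 had both channels well above background on only 1 of the 2 arrays, and at 6 h ARD3, AT1G07050, COR27, AT2G27420, LBD41, ERF71, TIP2;3, EXPA18 and XTH19. A probe not well above background in 1 channel on both arrays of a time point has only a bound. It is given as "at least N-fold", from the bright channel's mean over both arrays against the higher of the dim spot's own signal and the lowest signal well above background, per channel after loess and Aquantile normalization, and it is open to dye bias because dyes were not swapped.

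The steps were tested on simulated data: intensities with known changes, the measured backgrounds, a dye curve and independent noise with each probe's fitted spread were taken through the same steps. Of 67 genes changed 1.5-fold at 2 h, 0 were recovered. At 2-fold, 32 of 67 (47.8%) were recovered, and at 4-fold 64 of 66 (97.0%). At 6 h these counts were 6 of 67 (8.96%), 29 of 67 (43.3%) and 65 of 66 (98.5%). Of 19553 unchanged genes, 9 were called at each time. A simulated list shifted by 0.5 log2 was called by camera with the preset correlation (adjusted p = 1.63e-21) and not with the estimated one (adjusted p = 0.171). None (0) of the other simulated lists were called. Because the noise was independent, this cannot show how the preset correlation fares where members vary together. In the data the estimated correlation was −0.01 for the phenylpropanoid, 0.555 for the carbon starvation and 0.873 for the hypoxia list.

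Ratios at 2 h and at 6 h share control RNA. The correlation, covariance, share of genes with the same sign and overlap of calls were therefore set beside 100 simulations of unchanged treated samples against shared controls, in which a share of 0.5 of the spread was assumed to come from the control. For the overlap, lists of the observed sizes were also taken by p from the simulated samples, a comparison added after the overlap had been seen, as were shares of 0.1, 0.3, 0.7 and 0.9. The share was not measured directly, and the simulation gave arrays of the same replicate number the same control. Alternatives planned beforehand were no background correction, a normexp offset of 0, Agilent's log10 ratio, the authors' whole-series table, median centring in place of loess, Aquantile normalization between arrays, no filter, a stricter filter, outlier spots kept, an intensity trend in eBayes, the arrays of a time point alone, the replicate number as a block, a fold threshold of 2, each array left out in turn and, for lists, the mean over all kept probes of a gene. The planned background model with all spots became an alternative when the model was changed, after the data were seen, and a limit of 25 for the spots left out of it was added then, as were a list of aliphatic glucosinolate genes and a scan of 106 gene families by symbol stem. When an array was left out, the lone array of its time point was assumed to vary like those of the other time point. Agilent's spike-in spots were used only to check the dyes (correlation of measured with designed log ratios 0.990 to 0.996). Analyses were run in R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.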

Results

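Seedlings of Arabidopsis thaliana Col-0, 14 days old, were treated in water with 20 µM cis-cinnamic acid, the light-made isomer of trans-cinnamic acid, which is the first product of the phenylpropanoid pathway. cis-Cinnamic acid is known to alter plant growth in ways related to auxin. The RNA of seedlings treated for 2 h or 6 h was compared with that of seedlings collected at 0 h on 2-colour Agilent arrays, with 2 arrays at each time. The treated RNA was always in Cy5 and the 0 h RNA in Cy3. Median Cy5 intensities were 492 and 386 at 2 h and 403 and 351 at 6 h, and median Cy3 intensities were 228, 244, 212 and 242 on these arrays. From 65.3% to 69.0% of the spots were well above background in Cy5 and from 61.9% to 66.3% in Cy3. Values were obtained for 19973 genes. The number of arrays limits the precision. No seedlings without the compound were collected at 2 h or 6 h. The hour, the time in water and off the sucrose medium, and any effect of DMSO were therefore not separated from the compound. With Cy5 always the treated sample, a gene-specific dye effect also stayed in the ratios against 0 h. Across probes, the log2 ratios of the replicates had a correlation of 0.508 at 2 h and 0.662 at 6 h, and probes are not independent replicates.

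The comparison of 2 h with 0 h asked which transcripts changed early after the compound was given. GH3.3 (AT2G23170), an enzyme that joins auxin to amino acids, had the largest rise, 5.84 ± 0.23 in log2 (SE, n = 2 arrays; limma adjusted p = 0.0174). The other GH3 genes among the top 10 were GH3.1 (3.97 ± 0.19) and GH3.2, named BRU6 in the reference (at least 15.4-fold, because the control was not well above background, log2 3.94). MAKR4, a membrane-associated regulator linked to lateral roots, rose by 3.37 ± 0.18. GRX480, a glutaredoxin that binds TGA transcription factors, rose by 4.25 ± 0.18, and BAP2, an inhibitor of cell death, by 4.11 ± 0.34. The calcium pump gene AT3G22910 rose by 4.06 ± 0.16, ARD3 of the methionine salvage pathway by 3.94 ± 0.41, the glutathione S-transferase GSTU12 by 3.49 ± 0.33 and the calmodulin-like CML37 by 3.45 ± 0.29. The largest fall was that of GSTU28, another glutathione S-transferase (−1.80 ± 0.15). It was followed by AT1G36060, which encodes an AP2/ERF transcription factor (−1.68 ± 0.13), AT5G24100 (−1.65 ± 0.11) and AT5G40590 (−1.52 ± 0.13). AT4G31320 fell at least 2.78-fold and AT4G16270 at least 2.102-fold, with the treated sample not well above background. GSTU14 (−1.34), the phosphate transporter PHT1;1 (−1.24), AT5G26290 (−1.13) and the ferritin FER3 (−1.09) also fell. The adjusted p of these 20 genes ranged from 0.0174 to 0.049. On the coordinates of the deposited files (build ath1:Jan2004), the probe of GH3.3 lay on chromosome 2 from 9871102 to 9871161, that of GH3.1 on chromosome 2 from 6458786 to 6458845, that of GH3.2 on chromosome 4 from 17581069 to 17581128 and that of GRX480 on chromosome 1 from 10013620 to 10013679.

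At 2 h, 127 genes rose and 11 fell, all of them at least 2-fold. At an unadjusted p under 0.05 there were 1714 and 861 genes, against 999 in all that chance alone would give. These counts depended on a change of the background model that was made after the planned fit had been seen to give 0 genes here by limma (1596 at an unadjusted p under 0.05, lowest adjusted p = 0.109). In the planned fit, 8 spots of 2 h replicate 1 compressed the ratios of that array. Without any background correction, an alternative planned beforehand, 126 genes rose and 12 fell, and 129 of these 138 genes were among those called here. With either 2 h array left out, limma called 0 genes: without replicate 1 there were 1118 genes at an unadjusted p under 0.05 (lowest adjusted p = 0.449), and without replicate 2 there were 1407 (0.230). With median centring in place of loess, 300 genes rose and 29 fell. The median of all genes then lay at 0.21 at 2 h, at 0.27 at 6 h and at 0.07 for the difference between the times. Genes were still tested against 0 and not against that median, so the counts with median centring include this offset. With Agilent's own ratios 74 genes rose and 5 fell, and with only probes well above background in both channels on all arrays 53 and 3. With the replicate number as a block, 419 rose and 107 fell.

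Auxin-induced genes were among the groups with the highest ratios at 2 h. Of the 27 lists tested, camera called 14 at 2 h, 14 at 6 h and 8 between the times, of which 0 held with an estimated correlation. Fry called 1, 6 and 2. At 2 h its call was that of the early auxin-induced genes (adjusted p = 0.0423). The Aux/IAA (0.177), SAUR (0.248), touch and wound, carbon starvation and salicylate lists (0.178 each) did not pass it. Its calls at 6 h included the early auxin-induced, Aux/IAA, phenylpropanoid and flavonoid lists, and not the SAUR (0.125) or carbon starvation (0.0802) lists. Between the times fry called the phenylpropanoid list and not the SAUR list (0.163). The test with an estimated correlation had 2 residual degrees of freedom and also missed a simulated list shifted by 0.5 log2. Its adjusted p-values below therefore leave a list undecided and do not count against it. Of 18 measured GH3, LBD and other early auxin-induced genes, 7 rose over all genes and 15 when adjusted over the list alone, and 0 fell. Their median was 1.59 (camera adjusted p = 1.85e-14, adjusted p = 0.555 with an estimated correlation). LBD29, a transcription factor of lateral root formation, is counted among the 7, but only 1 array of 2 h gave a value for it (2.93). Its spread came from the 6 h arrays and the prior, and it no longer passed without either 6 h array. Of the other named genes, GSTU12, GSTU22, AT4G31320, AT4G16270, AT5G26290, PHT1;1, FER3, ERF71 and XTH19 also did not pass at 2 h in those fits. The ratios at 2 h stayed as given, because both 2 h arrays remained. Of 25 Aux/IAA genes, which encode repressors of auxin signalling, 0 passed in limma over all genes and 13 were higher at an unadjusted p under 0.05. Adjusted over the list alone, 12 rose, and the median was 0.47 (camera adjusted p = 3.52e-07, adjusted p = 0.555 with an estimated correlation). IAA19 had a log2 ratio of 1.79 (adjusted p = 0.0877) and IAA30 of 1.42 (0.0627). None (0) of the 29 SAUR genes, a family of small auxin-induced proteins, passed in limma over all genes or adjusted over the list alone, and 11 were higher at an unadjusted p under 0.05. The median of the family was 0.32 (camera adjusted p = 1.78e-05, adjusted p = 0.555 with an estimated correlation). Among 16 auxin transport genes 0 passed in limma over all genes (3 higher and 1 lower at an unadjusted p under 0.05, 3 higher adjusted over the list alone, median 0.05). Of the 16 genes of auxin synthesis, oxidation and perception 0 passed in limma, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (median −0.07, not called, but called lower with median centring at a median of 0.14, below the 0.21 of all genes, adjusted p = 0.0189). Beside these groups, the shoot markers had a median of 0.39 and the root markers one of −0.29.

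Genes of touch, wounding, defence and sugar starvation also had higher ratios at 2 h. Of 23 early touch and wound genes 7 rose, and 10 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 1.23e-05, adjusted p = 0.555 with an estimated correlation). Among them were CML38 (1.92 ± 0.12) and the transcription factor WRKY40 (2.47 ± 0.20). Of 19 salicylate and defence genes 2 rose, GRX480 and the transcription factor WRKY38 (3.27 ± 0.21). Adjusted over the list alone, 9 rose and 3 fell, and the median was 0.79 (camera adjusted p = 0.000156, adjusted p = 0.555 with an estimated correlation, and 0.0538 with median centring). That median was 1.09 on replicate 1 and 0.49 on replicate 2. Of 27 jasmonate genes 1 rose, CYP94B3, which oxidises the active jasmonate (2.37 ± 0.20), and 4 rose adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.000287, adjusted p = 0.555 with an estimated correlation). Of 22 ethylene genes 0 passed in limma over all genes or adjusted over the list alone (4 higher at an unadjusted p under 0.05, median 0.29, camera adjusted p = 0.00327, adjusted p = 0.555 with an estimated correlation). Of 19 carbon starvation genes 1 rose over all genes and 12 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 3.55e-10, adjusted p = 0.555 with an estimated correlation). ASN1, an asparagine synthetase induced in the dark, had a log2 ratio of 1.65 (adjusted p = 0.0905). The longer time off the sucrose medium was not separated from the compound. Of 26 photosynthesis and shoot markers 0 passed in limma over all genes (14 higher at an unadjusted p under 0.05), 10 rose adjusted over the list alone and the median was 0.39 (camera adjusted p = 5.1e-07, adjusted p = 0.555 with an estimated correlation).

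The root markers were among the lists with lower ratios at 2 h. Of 27 of them 1 fell, PHT1;1, and 7 fell adjusted over the list alone (median −0.29, camera adjusted p = 1.05e-06, adjusted p = 0.555 with an estimated correlation). Their median was −0.12 on replicate 1 and −0.52 on replicate 2. Of 19 nitrate response genes 0 passed in limma over all genes (2 higher and 7 lower at an unadjusted p under 0.05), and the same counts passed adjusted over the list alone. The nitrate median was −0.31 (camera adjusted p = 0.00385, adjusted p = 0.643 with an estimated correlation) and 0.04 with median centring, where the median of all genes was 0.21 and the list was also called lower (adjusted p = 0.0185). NRT2:1, the high-affinity nitrate transporter, had a log2 ratio of −2.37 (adjusted p = 0.0558). Of 16 flavonoid and anthocyanin genes 0 passed in limma (1 higher and 1 lower at an unadjusted p under 0.05), and 1 rose adjusted over the list alone, while the median was −0.32 (camera adjusted p = 0.00266, adjusted p = 0.555 with an estimated correlation). This call was lost without 2 h replicate 1 (0.111) and with the stricter filter (0.0593). Of 10 cytokinin genes 0 passed in limma (1 lower at an unadjusted p under 0.05), and 1 fell adjusted over the list alone (median −0.23, camera adjusted p = 0.0211, adjusted p = 0.643 with an estimated correlation), a call lost without 2 h replicate 1 (0.0605) and with no filter (0.0739). Of 16 genes of tryptophan, indole glucosinolates and camalexin 0 passed in limma (3 lower at an unadjusted p under 0.05), and 2 fell adjusted over the list alone (median −0.22, camera adjusted p = 0.0186, adjusted p = 0.643 with an estimated correlation). That call was lost without either 6 h array (0.0551), with Agilent's ratios (0.0546), with the authors' whole-series table (0.0543) and with the arrays of the time point alone (0.0547).

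The remaining lists were not called at 2 h. Of 30 glutathione S-transferases 2 rose and 1 fell, and 8 rose and 4 fell adjusted over the list alone (median 0.25). GSTU22 rose by 1.81 ± 0.19. GSTU14, named above, is not on this list. Of 24 xyloglucan hydrolases and expansins, which loosen cell walls, 2 rose, among them XTH19 (1.53 ± 0.15), and 5 rose and 2 fell adjusted over the list alone. The median of this list was −0.02 and its mean 0.16. Of 18 hypoxia genes 1 rose, the transcription factor gene ERF71 (1.67 ± 0.15), over all genes and adjusted over the list alone (median 0.11). In limma 0 passed over all genes among 17 other xenobiotic-response genes (3 higher and 2 lower at an unadjusted p under 0.05; 2 rose and 1 fell adjusted over the list alone; median 0.09). UGT73B4 had a log2 ratio of 2.27 ± 0.48 (adjusted p = 0.18) and UGT74E2 one of 1.66 ± 0.87 (0.547). The same count of 0 held for 22 abscisic acid genes (6 higher and 3 lower unadjusted, 4 higher adjusted over the list alone, median 0.13) and for 18 gibberellin and brassinosteroid genes (2 higher and 2 lower unadjusted, 0 adjusted over the list alone, median 0.02). It held for 20 phenylpropanoid genes (5 higher and 1 lower unadjusted, 0 adjusted over the list alone, median 0.02), and 11 evening-phased clock genes (2 higher and 1 lower, both unadjusted and adjusted over the list alone, median 0.07). For 12 morning-phased clock genes (median −0.09), 12 heat shock genes (median 0.00, mean −0.11) and 19 cell division genes (median 0.16) the count was 0 over all genes, adjusted over the list alone and at an unadjusted p under 0.05. None (0) of the 7 seed storage genes had a kept probe. Medians of lists called at 2 h that moved by more than 1.5 times without replicate 1 were also those of the ethylene (0.46), jasmonate (0.30), cytokinin (−0.12) and nitrate (−0.20) genes, and without replicate 2 those of the SAUR (0.49) and jasmonate (0.28) genes. Camera called 4 of these lists higher once 1 array was left out: hypoxia (adjusted p = 3.1e-05), other xenobiotic-response (0.00309) and cell division (0.0274) genes without 2 h replicate 1, and abscisic acid genes (9.5e-05) without 2 h replicate 2. The hypoxia list was also called with no filter (0.0298), with the replicate number as a block (0.0218) and with all spots in the background model (0.0383), and the glutathione S-transferases with the block (0.0312).

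**Figure D1:**
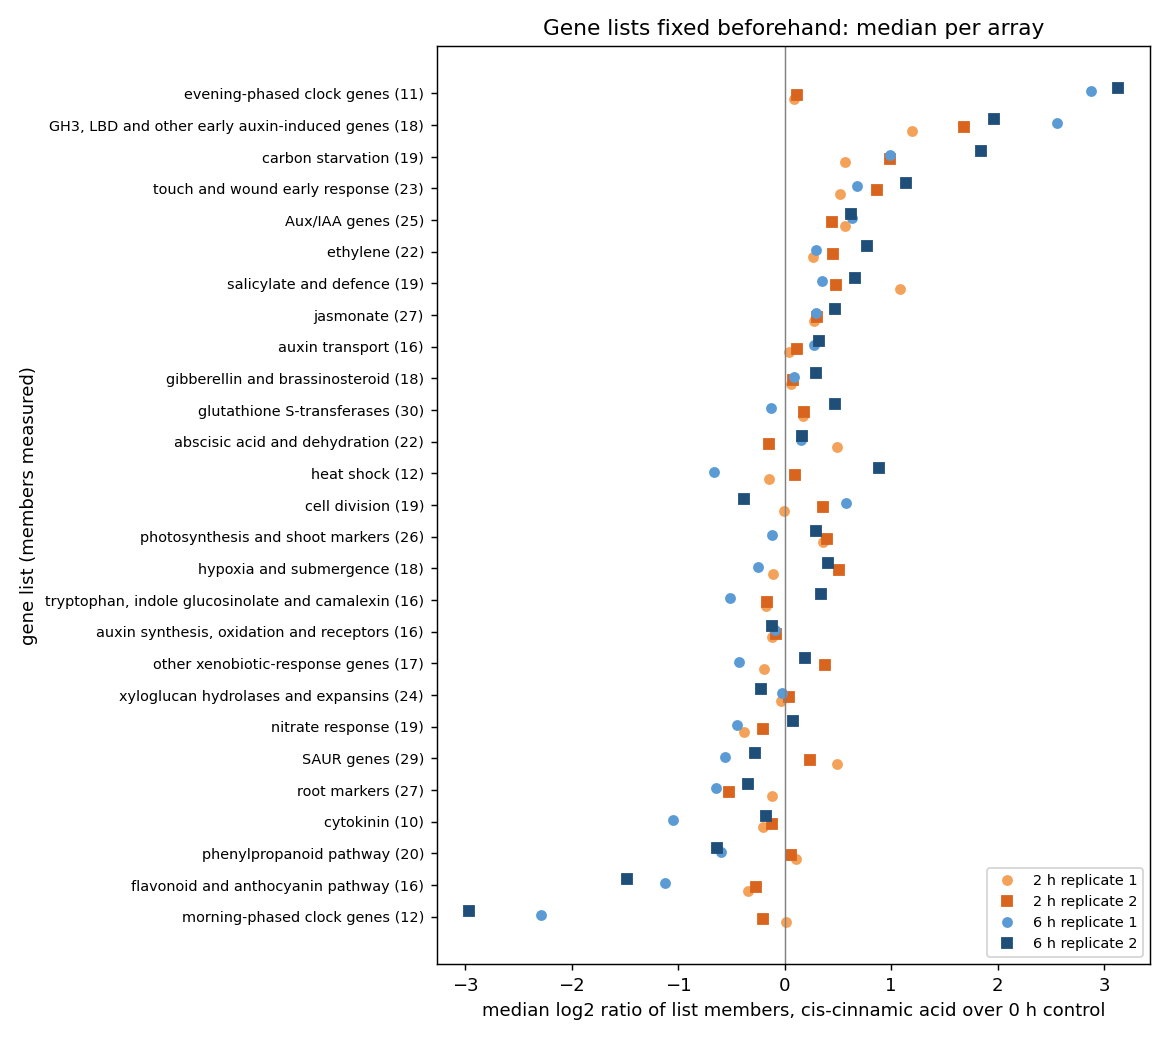
Median log2 ratio (x axis, cis-cinnamic acid over the 0 h control) of the members of each gene list (y axis, number measured in brackets), with 1 point for each of the 4 arrays. The evening-phased clock genes lay at 0.09 and 0.12 at 2 h and at 2.88 and 3.13 at 6 h, while the early auxin-induced genes lay between 1.198 and 2.56 on all 4 arrays.

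The comparison of 6 h with 0 h asked how far the response had gone after a longer treatment. GH3.3 was again among the genes with the largest rise (5.83 ± 0.23, adjusted p = 0.00191), with GH3.1 (5.08 ± 0.19). Genes of the evening rose and genes of the morning fell: the clock gene ELF4 rose by 4.52 ± 0.14, and CCA1 and LHY, a pair of transcription factors at the core of the morning loop of the clock, fell by 4.38 ± 0.23 and 4.34 ± 0.19. COR27, a cold-regulated gene that is also under the clock, rose by 5.08 ± 0.21. AT4G33980 rose by 5.50 ± 0.12, AT1G07050 by 5.30 ± 0.20, AT2G33830 by 5.20 ± 0.27, AT1G56300 by 4.45 ± 0.18 and AT5G23240 by 4.40 ± 0.19. AT4G25580 was at least 20.2-fold higher, with the control not well above background. The largest fall was that of AT2G15020 (−4.89 ± 0.12). It was followed by CCA1, COL2 (−4.35 ± 0.27), LHY and AT2G27420 (−4.12 ± 0.12). Falls were also measured for NRT1.5, which loads nitrate into the xylem (−3.97 ± 0.41), AT3G09450 (−3.85 ± 0.33), CYP79F1, the first step of aliphatic glucosinolate synthesis (−3.81 ± 0.13), AT3G12320 (−3.70 ± 0.17) and AT3G28270 (−3.59 ± 0.11). The adjusted p of these 20 genes ranged from 0.00191 to 0.00863. At 2 h, though not at 6 h, 2 other kept probes of AT3G28270 and 1 each of BR6OX2 and ERD9, had the opposite sign. The probe of ELF4 lay on chromosome 2 from 16741416 to 16741475, that of CCA1 on chromosome 2 from 19255709 to 19255768, that of LHY on chromosome 1 from 34018 to 34077 and that of CYP79F1 on chromosome 1 from 5611242 to 5611301.

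At 6 h, 1655 genes rose and 1538 fell, of which 774 and 691 changed at least 2-fold. With median centring in place of loess 5213 genes rose and 1058 fell, a share of 83.1% higher against 51.8%. These were tested against 0, while the median of all genes lay at 0.27, so the share includes that offset. Without 2 h replicate 1 or without 2 h replicate 2, 760 rose and 696 fell, and without 6 h replicate 2 the counts were 543 and 545. Of the 99 named genes that passed at 6 h, 62 passed whichever of the 4 arrays was left out, and the largest number of calls, 32, was lost without 6 h replicate 2 (adjusted p up to 0.152). Those that did not pass without 1 or more of the arrays were NRT1.5, IAA5, SAUR9, SAUR15, AT2G17500, LAX3, ABCB4, PIN3, YUC2, ERF6, ERF1, ARR15, BR6OX2, GA2OX2, GA20OX1, ERD9, CCR1, PAL2, DFR, CYP94B3, LOX2, WRKY38, SARD1, PR5, SUR1, UGT74B1, COR15B, RD26, NRT2:1, LHB1B2, LHCB2.1, TIP2;3, EXPA7, EXPA18, EXPB1, EXPA5 and HSP18.2. With the replicate number as a block, 2440 rose and 2411 fell.

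The clock genes moved apart. All 11 evening-phased clock genes rose, over all genes and adjusted over the list alone, with a median of 3.004 (camera adjusted p = 9.96e-13, adjusted p = 0.395 with an estimated correlation). Beside ELF4, the RNA-binding protein gene GRP7 rose by 4.28 ± 0.15 and the pseudo-response regulators PRR3 and PRR5 by 4.27 ± 0.13 and 4.02 ± 0.13. Of 12 morning-phased genes 10 fell, and adjusted over the list alone 10 fell and 1 rose, with a median of −2.59 (camera adjusted p = 2.91e-07, adjusted p = 0.536 with an estimated correlation). AT3G12320, known as LNK3, a partner of the morning transcription factors, was 1 of them.

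Early auxin-induced genes were still high. Of 18, 14 rose over all genes and adjusted over the list alone, with a median of 2.36 (camera adjusted p = 5.13e-09, adjusted p = 0.395 with an estimated correlation). GH3.2 was at least 19.3-fold higher and LBD29 at least 17.5-fold higher. Of 25 Aux/IAA genes 12 rose and 2 fell, and 15 rose and 3 fell adjusted over the list alone (median 0.53, camera adjusted p = 0.000284, adjusted p = 0.536 with an estimated correlation). IAA19 rose by 2.71 ± 0.25, IAA29 by 2.55 ± 0.18, IAA30 by 1.90 ± 0.16 and IAA5 by 1.59 ± 0.26. The SAUR genes lay on the other side of 0: of 29, 9 fell, and 12 fell adjusted over the list alone (median −0.39, camera adjusted p = 8.2e-05, adjusted p = 0.594 with an estimated correlation). SAUR9 (−1.59), AT2G21210 (−1.57), AT1G72430 (−1.18) and SAUR15 (−1.10, but −0.66 and adjusted p = 0.0601 without 6 h replicate 1) fell most. Of 16 auxin transport genes 5 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone (median 0.28, not called). The carrier genes AT2G17500 (1.77), LAX3 (1.04) and ABCB4 (0.93) rose and the efflux carrier PIN3 (−0.85) fell. Of 16 genes of auxin synthesis, oxidation and perception 1 fell over all genes and adjusted over the list alone, YUC2 (−1.05), an enzyme of auxin synthesis (list median −0.10, not called).

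Among the other hormones, ethylene genes were higher and cytokinin genes lower at 6 h. Of 22 ethylene genes 5 rose and 1 fell, over all genes and adjusted over the list alone (median 0.42, camera adjusted p = 0.000973, adjusted p = 0.538 with an estimated correlation). Their median was 0.29 on replicate 1 and 0.77 on replicate 2. The transcription factors ERF6 (2.00), ERF1 (1.67) and ERF2 (1.65) rose, and ACO1, an enzyme of ethylene synthesis, fell (−1.73). Of 10 cytokinin genes 3 fell, and 4 adjusted over the list alone (median −0.58, camera adjusted p = 0.0024, adjusted p = 0.594 with an estimated correlation), a call lost without 6 h replicate 1 (0.218, median −0.17), while without 6 h replicate 2 the median was −1.05. They were the response regulators ARR9 (−1.22), RR3 (−1.03) and ARR15 (−0.87). Of 27 jasmonate genes 8 rose and 1 fell, and 11 rose and 2 fell adjusted over the list alone (median 0.33, camera adjusted p = 0.00284, adjusted p = 0.594 with an estimated correlation, and 0.138 with median centring). The repressor JAZ7 (3.46) and CYP94C1 (2.37), which oxidises the active jasmonate, rose, and LOX2, a lipoxygenase of jasmonate synthesis, fell (−1.73). Of 19 salicylate and defence genes 2 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (median 0.45, camera adjusted p = 0.0326, adjusted p = 0.698 with an estimated correlation). WRKY38 (1.57) and SARD1 (1.32) rose and PR5 (−1.06, but −0.63 and adjusted p = 0.0982 without 6 h replicate 2) fell. This call was lost without 6 h replicate 2 (0.470), with median centring (0.298) and with all spots in the background model (0.0547). Of 18 gibberellin and brassinosteroid genes 5 rose and 3 fell, and 6 rose and 3 fell adjusted over the list alone (median 0.25, not called). The brassinosteroid gene BR6OX2 (−1.34) and the gibberellin synthesis genes GA3OX1 (−1.17) and GA20OX1 (−1.10, but −0.72 and adjusted p = 0.0797 without 6 h replicate 1) fell and GA2OX2, which inactivates gibberellins, rose (1.29). Of 22 abscisic acid genes 4 rose and 3 fell, and 6 rose and 4 fell adjusted over the list alone (median 0.17, not called). COR15B (2.31) and RD26 (1.53) rose, and RD22 (−1.25) and the phosphatase HAB1 (−1.10) fell.

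The phenylpropanoid pathway, which uses trans-cinnamic acid, was lower at 6 h, and so were the root markers (median −0.51, camera adjusted p = 0.0015, adjusted p = 0.594 with an estimated correlation). Of 20 genes of the pathway 11 fell, and 16 adjusted over the list alone (median −0.63, camera adjusted p = 2.75e-07, adjusted p = 0.395 with an estimated correlation). They included ATCAD4 (−1.54 ± 0.13), UGT84A1 (−1.35 ± 0.16), CCR1 of lignin synthesis (−1.14 ± 0.14) and PAL2, which makes cinnamic acid (−1.03 ± 0.12). Of 16 flavonoid and anthocyanin genes 11 fell, and 13 adjusted over the list alone (median −1.21, camera adjusted p = 1.05e-06, adjusted p = 0.395 with an estimated correlation). F3H fell by 1.91 ± 0.15, the chalcone synthase TT4 by 1.74 ± 0.13 and FLS1 by 1.73 ± 0.14, and DFR was at least 4.93-fold lower. Of 16 genes of tryptophan, indole glucosinolates and camalexin 3 fell, over all genes and adjusted over the list alone: the transcription factor MYB34 (−2.13), SUR1 (−0.80) and UGT74B1 (−0.71). The median of that list was 0.01 and its mean −0.05, and it was not called. Of 30 glutathione S-transferases 2 rose and 7 fell, and 5 rose and 9 fell adjusted over the list alone (median 0.30, mean 0.08, not called). ERD9 (−3.14) and GSTU20 (−2.89) fell most and GSTU22 (2.11) rose. Of 17 other xenobiotic-response genes 0 passed in limma over all genes or adjusted over the list alone (1 lower at an unadjusted p under 0.05, median −0.13).

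Carbon starvation genes rose together at 6 h: of 19, 15 rose over all genes, and 17 rose and 1 fell adjusted over the list alone (median 1.36, camera adjusted p = 2.66e-08, adjusted p = 0.573 with an estimated correlation). The aminotransferase BCAT-2 rose by 4.16 ± 0.48, SEN1 (AT4G35770) by 3.22 ± 0.40, ASN1 by 2.84 ± 0.24 and MCCA, which breaks down leucine, by 2.37 ± 0.30. The treated seedlings had been off the sucrose medium for longer than the 0 h control, and this was not separated from the compound. Of 23 early touch and wound genes 9 rose, and 14 adjusted over the list alone (median 0.89, camera adjusted p = 3.37e-06, adjusted p = 0.538 with an estimated correlation). WRKY40 rose by 2.32 ± 0.20, CML38 by 1.27 ± 0.12 and CBF1 at least 3.54-fold. Of 27 root markers 8 fell, and 11 fell and 2 rose adjusted over the list alone (median −0.51, camera adjusted p = 0.0015, adjusted p = 0.594 with an estimated correlation), among them the root hair genes SHV2 (−2.24), EXPA7 (−1.75) and EXPA18 (−1.37) and the aquaporin TIP2;3 (−2.07). The 26 shoot markers had a median of 0.08 and were not called. Of these, 6 rose and 7 fell, and 9 rose and 9 fell adjusted over the list alone. LHB1B1 (2.06) and LHB1B2 (1.19) rose and LHCB2.3 (−1.12) and LHCB2.1 (−1.07), which also encode light-harvesting proteins, fell. Of 19 nitrate response genes 4 rose and 3 fell, and 5 rose and 7 fell adjusted over the list alone (median −0.21, mean 0.06, not called). BT2 (3.88) and AT1G25550 (1.48) rose, and NRT2:1 (−1.88) and HRS1 (−1.46) fell.

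In the remaining lists, of 24 xyloglucan hydrolases and expansins 3 rose and 3 fell, and 3 rose and 6 fell adjusted over the list alone (median −0.16, not called). The falls were those of EXPB1 (−1.90), EXPA5 (−1.79) and XTH33 (−1.74). EXPB1 did not pass without 6 h replicate 1 (adjusted p = 0.0539) or replicate 2 (0.114). Without 6 h replicate 2 EXPA5 had −1.09 (0.118), and it did not pass without either 2 h array (0.0787). Of 18 hypoxia genes 1 rose over all genes and adjusted over the list alone, LBD41 (1.78), and the list was not called (median 0.03). Of 12 heat shock genes 2 fell over all genes and adjusted over the list alone, GolS1 (−1.33) and HSP18.2 (−0.74), while the median was 0.14. That list was not called with all arrays and was called lower without 6 h replicate 2 (adjusted p = 0.0295, median −0.66). Of 19 cell division genes 0 passed in limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (median 0.17), and CYCD3;1 had a log2 ratio of 0.40 and PLE one of 0.36. The cell division list was called lower without 6 h replicate 1 (adjusted p = 0.00367, median −0.38) and higher without 6 h replicate 2 (3.72e-06). Other lists not called with all arrays were hypoxia, called higher without 6 h replicate 1 (0.0275), and the xenobiotic-response (0.00944) and tryptophan and indole (0.0113) genes, called lower without 6 h replicate 2.

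**Figure D2:**
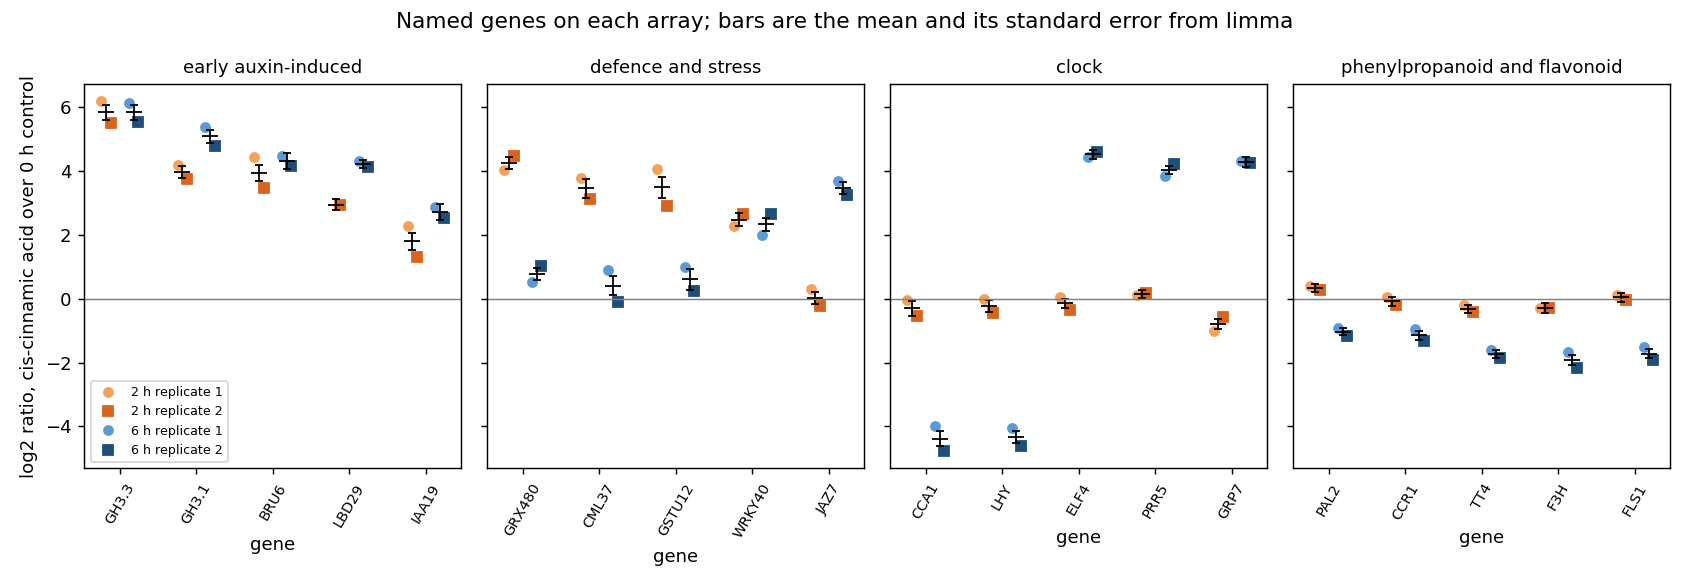
Log2 ratio (y axis, cis-cinnamic acid over the 0 h control) of 5 named genes in each of 4 groups (x axis), with points for the arrays and bars for the mean and its standard error from limma. GH3.3 lay near 5.84 at 2 h and 5.83 at 6 h, GRX480 at 4.25 and 0.77, and CCA1 at −0.30 and −4.38.

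The comparison of 6 h with 2 h asked which genes differed between the times. A dye effect that is the same on every array cancels in it. AT1G07050 (5.47) was higher at 6 h than at 2 h by the most and AT2G15020 (−4.59) lower by the most. For AT1G07050 both channels were well above background on only 1 array at each time. Clock genes were among those that differed most: GRP7 was higher at 6 h than at 2 h by 5.07 ± 0.21 (adjusted p = 0.0198) and ELF4 by 4.67 (0.0198), and COL2 (−4.21, 0.0294), LHY (−4.11, 0.0207) and CCA1 (−4.08, 0.0254) were lower. AT1G56300 (4.61) was also higher, and AT3G12320 (−3.67) lower. COR27 passed as higher too (0.0207), but its control was not well above background at 2 h, so no size is given. Of 11 evening-phased genes 10 were higher at 6 h than at 2 h, and 11 adjusted over the list alone (median 2.48, camera adjusted p = 3.03e-20, adjusted p = 0.411 with an estimated correlation). Of 12 morning-phased genes 8 were lower, and 10 adjusted over the list alone (median −2.49, camera adjusted p = 6.61e-10, adjusted p = 0.595 with an estimated correlation). In all, 141 genes were higher and 158 lower at 6 h than at 2 h. Limma gave 0 genes without 2 h replicate 1 (1702 at an unadjusted p under 0.05), without 2 h replicate 2 (2213) and without 6 h replicate 2 (3437), and 26 higher and 20 lower without 6 h replicate 1. With Agilent's own ratios 40 were higher and 53 lower, with a normexp offset of 0 there were 86 of each, and with the replicate number as a block 484 and 667.

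Camera called 6 other lists between the times, and the Aux/IAA, auxin transport and auxin synthesis lists were not among them. Of 29 SAUR genes 0 passed in limma over all genes (19 lower at an unadjusted p under 0.05), and 16 were lower at 6 h than at 2 h adjusted over the list alone (median −0.86, camera adjusted p = 5.89e-11, adjusted p = 0.603 with an estimated correlation). Of 18 early auxin-induced genes 2 were higher, and 6 adjusted over the list alone (median 0.37, camera adjusted p = 0.00301, adjusted p = 0.603 with an estimated correlation, 0.166 with the stricter filter and 0.0994 with an intensity trend). Of 20 phenylpropanoid genes 1 was lower, PAL2 (−1.36), and 14 adjusted over the list alone (median −0.64, camera adjusted p = 6.61e-10, adjusted p = 0.411 with an estimated correlation). Of 16 flavonoid genes 2 were lower, FLS1 (−1.77) and TT4 (−1.42), and 5 adjusted over the list alone (median −0.86, camera adjusted p = 1.32e-06, adjusted p = 0.528 with an estimated correlation). Of 19 carbon starvation genes 0 passed in limma over all genes (9 higher and 2 lower at an unadjusted p under 0.05), and 8 were higher and 2 lower adjusted over the list alone (median 0.67, camera adjusted p = 0.000907, adjusted p = 0.818 with an estimated correlation). That call was lost without 6 h replicate 2 (0.104, median 0.32), and without 6 h replicate 1 the median was 1.01. Of 26 shoot markers 1 was lower, LHCB2.3 (−1.47), and 7 adjusted over the list alone (median −0.24, camera adjusted p = 0.0082, adjusted p = 0.818 with an estimated correlation). That call was lost without 6 h replicate 1 (0.317, median −0.12) and with Agilent's ratios (0.0757). Without 2 h replicate 2 the flavonoid median was −0.54. The root markers had a median of −0.08 in this comparison and were not called.

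The other lists were not called between the times, and in 3 of them the signs of median, mean or test differed. These were the gibberellin and brassinosteroid genes (median 0.05, mean −0.04), the auxin synthesis genes (median −0.03, mean −0.09, test upward) and the cell division genes (median −0.03, mean 0.01). The cell division list was called lower without 6 h replicate 1 (adjusted p = 0.000257, median −0.46) and higher without 6 h replicate 2 (1.48e-05). With the replicate number as a block, ethylene (adjusted p = 0.0162) and nitrate genes (0.0337) were called higher, and other xenobiotic-response genes (0.012), xyloglucan hydrolases and expansins (0.0272) and glutathione S-transferases (0.0285) lower. With median centring glutathione S-transferases (0.00866), xyloglucan hydrolases and expansins (0.0377) and cytokinin genes (0.0379) were called lower, and with no filter glutathione S-transferases and cytokinin genes (both 0.0401). With all spots in the background model Aux/IAA and ethylene genes (both 0.0489) were called higher and cytokinin genes (0.0327) lower. Leaving out 1 array also brought calls of other lists. Without 2 h replicate 1 these were Aux/IAA (higher, 0.0347), glutathione S-transferases (lower, 0.0347), hypoxia (lower, 0.0347) and xenobiotic-response genes (lower, 0.000983), and without 2 h replicate 2 salicylate genes (lower, 0.0354). Without 6 h replicate 1 they were ethylene (0.00795), nitrate (0.00888), tryptophan and indole (0.0225) and heat shock genes (0.0326), all higher, and xyloglucan hydrolases and expansins (lower, 0.0326). Without 6 h replicate 2 they were cytokinin (0.000267), xenobiotic-response (0.000795), glutathione S-transferase (0.00115), salicylate (0.019) and hypoxia genes (0.0377), all lower. All the members of lists not called that passed are given here, whether or not the rule named them. JAZ7 was higher at 6 h than at 2 h by 3.43 (adjusted p = 0.0245), EXPA17 by 2.17 (0.0279), PHT1;1 by 1.45 (0.0464) and ERF2 by 1.37 (0.0421). GRX480 (−3.48, 0.0245), LOX2 (−2.36, 0.0363), GSTU20 (−2.32, 0.0229), XTH19 (−1.72, 0.0447), GSTU6 (−1.62, 0.0386), GolS1 (−1.58, 0.0404), XTH17 (−1.30, 0.0464) and HAB1 (−1.19, 0.0471) were lower.

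Of the 127 genes that rose at 2 h, 20 were lower at 6 h than at 2 h, 4 were higher and 103 did not differ by the test. The 20 included GRX480, with 4.25 at 2 h and 0.77 at 6 h (difference −3.48, adjusted p = 0.0245), AT3G22910 (−2.096, 0.036) and XTH19. Of the 11 genes that fell at 2 h, AT1G36060 (1.95, adjusted p = 0.0304) and PHT1;1 (1.45, 0.0464) were higher at 6 h than at 2 h.

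**Figure D3:**
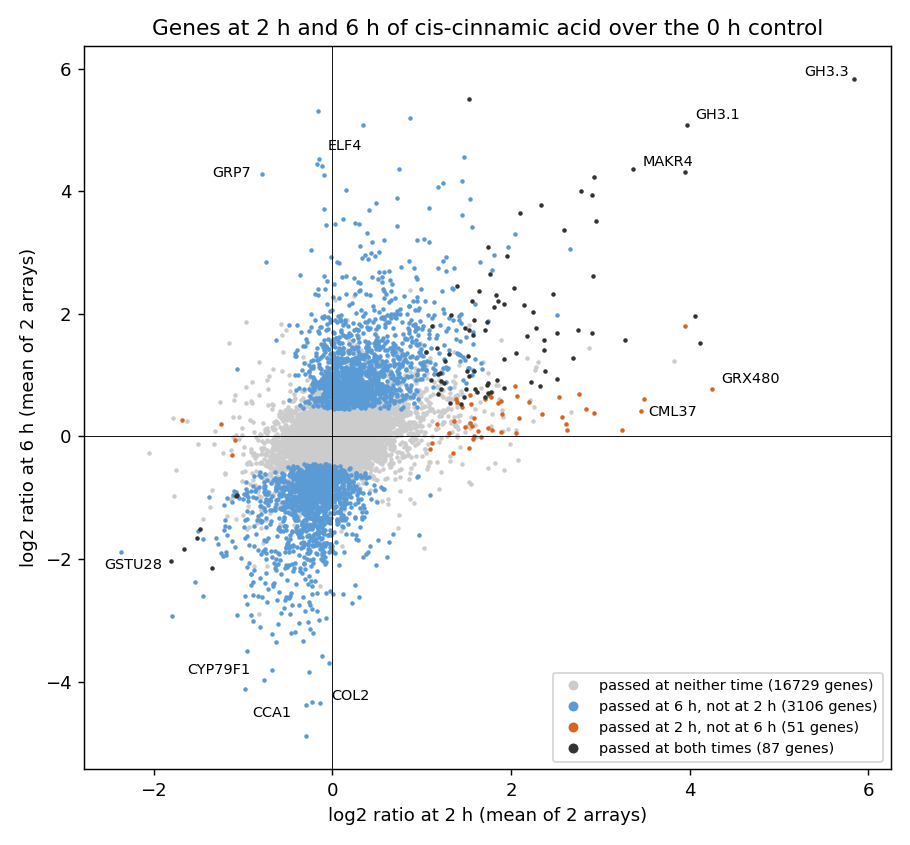
Log2 ratio at 2 h (x axis) against that at 6 h (y axis), both over the 0 h control and means of 2 arrays, with 1 point per gene coloured by the time at which it passed the test. Of 127 genes that rose at 2 h, 80 also rose at 6 h, such as GH3.3 (5.84 and 5.83), while GRX480 had 4.25 at 2 h and 0.77 at 6 h.

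The ratios of 2 h and 6 h were set against each other across genes, which are not independent replicates, and both rest on the same kind of control RNA. Unchanged samples with shared controls were simulated with an assumed share of the spread from the control, which no array measured alone. The simulation gave same-numbered arrays the same control, which the labels do not state. Deviations from the group means of same-numbered arrays had a correlation of 0.43 across genes. That value estimates the share only if these arrays held the same control RNA and shared nothing else. Over 19786 genes the correlation was 0.51. The simulated correlation restates the assumed share: with a share of 0.5 it was 0.50 on average over 100 simulations (SD 0.0288), and it ran from 0.10 at a share of 0.1 to 0.90 at a share of 0.9, so it gives no chance value for the observed one. The covariance was 0.111 against 0.0302 in the simulation with a share of 0.5, a difference of 0.0807, and the difference was 0.105 at a share of 0.1 and 0.0562 at a share of 0.9. The same sign was seen in 70.4% of the genes, against 66.7% at a share of 0.5 and from 53.2% to 85.6% over the other shares. Of the 127 genes that rose at 2 h, 80 also rose at 6 h, and 0 passed as lower in limma. Lists of these sizes with the lowest p would share 10.52 genes if they were independent. In simulated unchanged samples they shared 87.1 on average (SD 4.84) at a share of 0.5, 45.2 at a share of 0.1 and 125 at a share of 0.9. Of the 11 that fell at 2 h, 7 fell at 6 h, against 0.847 for independent lists and 8.70 (SD 1.35) in the simulation with a share of 0.5, with 4.77 to 10.9 over the other shares. In the samples simulated with a share of 0.5, limma called 0 genes at either time. How much of the overlap comes from the shared controls is therefore left open. Arrays of the same replicate number had correlations of 0.42 and 0.57 and those of different numbers 0.26 and 0.38.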

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

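Of the tests reported here, those of the hour of sampling, of the dye by the difference between the times, of the shoot share and of the background model were chosen only after the result had been seen. The genes given with a difference of 6 h minus 2 h differed between the times by the limma test (141 genes higher and 158 lower at 6 h). The lists did so by camera with its preset correlation (8 lists called, and 0 with an estimated correlation on 2 residual degrees of freedom).

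Among the gene lists, those of the clock had the largest medians between 6 h and 2 h: the evening-phased list had a median of 2.48 and the morning-phased list one of −2.49 (adjusted p = 0.411 and 0.595 with an estimated correlation). A gene-specific dye effect is argued against, because it cancels between the times and both lists still differ, by 2.478 (lower quartile 1.98) and −2.489 (upper quartile −1.70). The loess step is argued against too, since the gap between the lists at 6 h was 5.698 with median centring alone. The later hour of sampling cannot be told apart from the treatment, because no untreated seedlings were collected at 6 h; the gap between the lists was 5.597 at 6 h. These values are consistent with a change by the time of day, which may account for part of the other changes at 6 h.

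The early auxin-induced genes were already higher at 2 h, with a median of 1.59 (adjusted p = 0.555 with an estimated correlation). A dye effect unrelated to gene function is argued against: the highest median among 10000 random lists matched on intensity was 0.2725. On the loess values a larger share of shoot tissue in the treated sample is argued against, since the list median lay 1.03 above the upper quartile of the shoot markers (0.56). With median centring the upper quartile of the shoot markers was not computed, so a larger shoot share was not tested there. In that setting the shoot markers had a median of 0.92 at 2 h and the list one of 1.68. The later hour or the longer time in water cannot be told apart from the compound without untreated seedlings, although the gap between evening and morning clock genes was only 0.1535 at 2 h. An effect of the compound on these genes stays an open hypothesis, which the design cannot separate from the hour, the water or DMSO.

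The planned fit with all spots in the background model called 0 genes at 2 h by limma (1596 at an unadjusted p under 0.05). With all spots, the spread of repeated spots on 2 h replicate 1 was 0.2661 of that on the other arrays, and 0.991 without the 8 spots, which is consistent with a background model pulled by those spots. Weaker ratios on that array from the start are argued against, since the SD of Agilent's own ratios there was 1.082 times that of 2 h replicate 2. No biological explanation was tested for this pattern.

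Camera called other lists between the times with its preset correlation, and 0 of them with an estimated correlation (adjusted p = 0.411 to 0.818). The median difference of 6 h minus 2 h was 0.37 for the early auxin-induced genes, −0.86 for the SAUR genes, −0.64 for the phenylpropanoid genes, −0.86 for the flavonoid genes, 0.67 for the carbon starvation genes and −0.24 for the shoot markers.

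Among single genes of or near the clock, the difference was 5.07 for GRP7, 4.67 for ELF4, 4.36 for PRR3, 3.87 for PRR5, −4.08 for CCA1, −4.21 for COL2, −4.11 for LHY and −3.67 for AT3G12320. Other genes higher at 6 h than at 2 h were AT1G07050 (5.47), AT1G56300 (4.61), AT5G23240 (4.52), AT2G33830 (4.33), AT4G33980 (3.97), JAZ7 (3.43), AT1G36060 (1.95), PHT1;1 (1.45), EXPA17 (2.17) and ERF2 (1.37). COR27 and AT4G25580 passed as higher too, with fitted differences of 4.74 and 3.09, but COR27's control was not well above background at 2 h and AT4G25580's at either time, so these are not measured sizes. Genes lower at 6 h than at 2 h were AT2G15020 (−4.59), AT3G28270 (−3.48), GRX480 (−3.48), AT2G27420 (−3.14), CYP79F1 (−3.14), LOX2 (−2.36), GSTU20 (−2.32) and AT3G22910 (−2.10). Smaller falls between the times were those of FLS1 (−1.77), XTH19 (−1.72), GSTU6 (−1.62), GolS1 (−1.58), LHCB2.3 (−1.47), TT4 (−1.42), PAL2 (−1.36), XTH17 (−1.30) and HAB1 (−1.19). All of these calls were lost without either 2 h array and without 6 h replicate 2, but each such fit leaves 1 array at a time point, which can itself end calls. Differences without these arrays were read only for the 10 genes named for this comparison. Without 2 h replicate 1, 2 h replicate 2 and 6 h replicate 2, in this order, they were 4.84, 5.30 and 5.11 for GRP7. They were 4.86, 4.48 and 4.60 for ELF4, and −4.46, −4.73 and −4.67 for AT2G15020. For COL2 they were −4.009, −4.417 and −3.715, against −4.21 with all arrays. Of the 10 genes named for this comparison, 0 turned.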

How the results depend on the processing

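The background model behind the reported values, which leaves out 8 spots of 2 h replicate 1, was chosen after seeing the data. This made the planned model with all spots an alternative, and the alternative limit of 25 for such spots and the further control shares in the simulation of shared controls were also added after seeing the data; the remaining alternatives were planned. The model as planned, with all spots, called 0 genes at 2 h (0 higher and 0 lower, with 1596 at an unadjusted p under 0.05 by limma), and it was changed after that was seen. At 6 h the planned model called 1751 higher and 1578 lower, and between the times 133 and 142. Of the values for named genes, 30 lost their call with it, and 9 that were not past the threshold moved by more than their spread. With no background correction 126 genes were higher and 12 lower at 2 h, and with a limit of 25 there were 133 and 13. At 2 h the counts moved to 74 and 5 with Agilent's ratios, 72 and 5 with the authors' whole-series table, 300 and 29 with median centring, 53 and 3 with both channels well above background on all arrays (fewer probes tested) and 249 and 26 at least 2-fold on both arrays without a test. At 6 h they moved to 5213 higher with median centring, 761 and 696 with the arrays of the time point alone (fewer arrays behind the spread), 774 and 691 with a 2-fold threshold added and 594 and 509 at least 2-fold on both arrays without a test. Between the times they moved to 86 and 86 with a normexp offset of 0, 40 and 53 with Agilent's ratios or the whole-series table, and 248 and 317 at least 2-fold on every pair of arrays without a test. With the replicate number as a block, 419 and 107 were called at 2 h, 2411 lower at 6 h and 484 and 667 between the times, and 13 lists between the times; deviations from the group means of same-numbered arrays had a correlation of 0.43 across genes. Leaving out 1 array gave 0 to 109 higher and 0 to 9 lower at 2 h, 543 to 1319 and 545 to 1117 at 6 h, 0 to 26 and 0 to 20 between the times, and 9 to 13 lists called between the times, with fewer arrays behind the spread and the lone array assumed to vary like the others. With an estimated correlation, tested on 2 residual degrees of freedom, 0 lists were called at each time and between them. Fry called 1, 6 and 2. The correlation of 2 h with 6 h ranged from 0.368 to 0.532 without 1 array and was 0.321 between arrays of different replicate number. Neither the cell division nor the heat shock list was called with all arrays. The cell division list was called lower without 6 h replicate 1, at 6 h (adjusted p = 0.00367) and between the times (0.000257), and higher without 6 h replicate 2 (3.72e-06 and 1.48e-05); leaving out 1 array gave it 3.72e-06 to 0.544 at 6 h and 1.48e-05 to 0.35 between the times. The heat shock list at 6 h was called lower without 6 h replicate 2 (0.0295), and its range was 0.0295 to 0.903. Except where fewer probes or arrays are named, the cause was not tested. Of the 1674 values for lists, 1545 kept their side of the threshold, 84 lost the call, 42 gained one and 3 were called in the opposite direction. Of the 4041 values for named genes, 3596 kept their side of the threshold, 303 lost the call and 22 gained one. Another 120, past the threshold in neither fit, moved by more than their spread. Of the named genes past the threshold in either fit, 0 turned. For values past it in neither fit, a change of direction was not counted. Only 61.9% to 69.0% of the spots were well above background in a channel, and where 1 channel was not, only bounds can be given.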

Other observations

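The aliphatic glucosinolate list and the scan of gene families were chosen only after the data had been seen, and the test of the remaining pathway members was written before their values were read. CYP79F1 (−3.81), IPMI2 (−3.06) and GSTU20 (−2.89), 3 genes of aliphatic glucosinolate synthesis, were seen first among the falls at 6 h. Of 16 further genes of the pathway, 15 fell at 6 h, with a median of −2.195 (camera p = 1.69e-14, p = 0.112 with an estimated correlation). They included IMS2 (−3.21), BCAT4 (−2.75), the transporter gene BAT5 (−2.74), CYP83A1 (−2.32), MAM1 (−2.25) and the transcription factors MYB29 (−2.14) and MYB28 (−0.85). IIL1 had a log2 ratio of −0.73 (adjusted p = 0.0507). At 2 h the median was −0.58 and 0 of the 16 passed in limma. Between the times 5 were lower at 6 h than at 2 h, with a median of −1.59. A fall shared by the pathway may be part of the response at 6 h, with the hour of sampling left open as for the clock genes.

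Among 106 gene families grouped by the stem of their symbols, camera called 13 at 6 h, 7 upward and 6 downward, and 0 with an estimated correlation. Among the families that were lower, 7 of 26 arabinogalactan proteins (AGP) fell (median −0.41), 3 of 12 fasciclin-like proteins (FLA, −0.60), 6 of 34 TBL genes (−0.25), 4 of 18 aquaporins of the plasma membrane (PIP, −0.38), 5 of 14 SAUR genes (−0.42) and 6 of 14 MES genes (−0.42, with 1 that rose). The cell wall families XTH, EXPA and IRX were not called at 6 h. Among the families that were higher, 5 of 12 ATL genes rose (median 0.76) and 2 of 19 autophagy genes (ATG, 0.25). At 2 h 10 families were called, 5 in each direction, and 0 with an estimated correlation, among them the WRKY transcription factors, of which 5 of 55 rose.

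In 8 lists the medians of the 6 h arrays lay on opposite sides of 0. On replicate 1 and replicate 2 they were −0.66 and 0.89 for heat shock, 0.57 and −0.38 for cell division, −0.51 and 0.34 for tryptophan and indole, −0.25 and 0.40 for hypoxia, −0.42 and 0.19 for other xenobiotic-response genes, −0.13 and 0.47 for glutathione S-transferases, −0.45 and 0.08 for nitrate and −0.12 and 0.29 for shoot markers. The cytokinin list had −1.05 and −0.17. Opposite signs were not particular to 6 h. On the 2 h arrays the medians were 0.49 and −0.14 for abscisic acid, −0.11 and 0.51 for hypoxia and −0.19 and 0.38 for other xenobiotic-response genes. They were also 0.01 and −0.20 for morning-phased clock genes and −0.15 and 0.09 for heat shock. For cell division they were −0.001 and 0.36, and for xyloglucan hydrolases and expansins −0.03 and 0.04.

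In the authors' whole-series table, 20, 1, 4 and 3 spots of the 4 arrays held a value other than the scanner's (beyond 0.001 in log10 or 1%), and each of these equalled the value of a neighbouring spot.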
